A study of Mus musculus with 12 samples.

How the data were processed

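RNA was measured by 10x Visium, which captures polyadenylated transcripts at their 3′ end on a grid of 55 µm spots, in 12 coronal brain sections of 10 µm thickness from mice. All mice carried loxP-flanked Inpp5d and the tamoxifen-inducible Cre recombinase CreER in the Cx3cr1 locus, a microglial driver. PSAPP mice also carried the APP KM670/671NL and PSEN1 exon 9 deletion transgenes, a model of amyloid plaque formation, and WT mice did not. Per the labels, mice received corn oil (CO) or 75 mg/kg tamoxifen (TAM) on 5 consecutive days at 3 months of age. The 4 groups were WT_CO, WT_TAM, PSAPP_CO and PSAPP_TAM, with 3 sections each. The labels do not state that the sections came from separate animals, so every p-value measured only the spread between these sections. The groups share the replicate numbers 1, 2 and 3, and the labels do not say what a number marks. Deviations from the group means correlated more between sections of the same number than between others, with medians of 0.15 against -0.079 in the cortex and 0.136 against -0.081 in the hippocampus. Mitochondrial transcripts made up 11.67 to 12.85% of UMIs in the sections numbered 3 and 6.75 to 10.49% in the others. All 3 pairs of a comparison exceeded a correlation of 0.1, the limit for pairing, for WT_TAM against WT_CO in the whole section (0.189, 0.182 and 0.142) and for PSAPP_TAM against PSAPP_CO in the hippocampus (0.114, 0.134 and 0.218), and for no other comparison. This pairing comes from the values and not from the labels, and the main fits, fixed in advance, had no block.

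Per the submitters' processing notes, reads were aligned to mm10 and counted with Space Ranger 1.3.1. The values deposited are counts of unique molecular identifiers (UMIs) per gene and spot, per the file headers, over 32285 genes. 2 matrices were deposited per section, one of spots under tissue and a second one. For 11 sections the second matrix had the same size as the tissue matrix. For the library labelled WT_TAM 2 it covered all 4992 positions of the array. The headers of the second matrices name software version 1.2.1, except that of WT_TAM 2, which names version 4. The tissue matrices were used for every comparison. Genes were identified by symbol, and the 78 IDs that share a symbol were kept apart by their ID. The files give gene identifiers but no positions. Clec7a, Mx1 and 1500015O10Rik were not analysed here.

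Sections held 2416 to 3513 tissue spots and 47.76 to 96.65 M UMIs (M, mega), with medians of 16410 to 31938 UMIs per spot. Group means were 61.1 ± 11.7, 77.9 ± 16.7, 73.5 ± 11.6 and 76.5 ± 16.5 M UMIs (SD, n = 3) in WT_CO, WT_TAM, PSAPP_CO and PSAPP_TAM. Mitochondrial transcripts made up 6.75 to 12.85% of UMIs. Inpp5d, among the lowest of the genes named in every comparison, rested on 184 to 677 UMIs per section. Levels are given in CPM, the count scaled by the normalised library size of the section or area as edgeR computes it.

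Spots were assigned to regions with scanpy 1.11.5 and leidenalg 0.10.2. The 33853 spots with at least 500 UMIs were clustered together over all sections (log-normalised counts, 2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 0.8), and 180 spots fell under the minimum. The 237 genes of the glial, immune, transgene and sex-linked lists, and mitochondrial genes, were left out of the clustering. A cluster took the name of the region whose marker list had members among its 10 leading genes (at least 20 CPM, pseudocount 2) and at least 3 members higher by 0.5 log2 units, or 5 where 1 led. Cortex, hippocampus, white matter, thalamus, hypothalamus, striatum, amygdala and piriform area, meninges and vessels, ventricle and choroid plexus, and habenula were named in this way, and 6 clusters stayed unnamed. 1 cluster of 207 spots was led by Cst7, Ccl6, Ccl3, Tyrobp and Cd52. Its spots took the region of the spots around them. A Visium spot covers several cells, so regions are shares of spots and no spot is a single cell.

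Counts were summed per section over all tissue spots and over the spots of the cortex, hippocampus and white matter. Genes were tested with edgeR 4.0.16 (R 4.3.3) after its filter on low counts by group, with TMM factors and quasi-likelihood tests over all 12 sections. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The comparisons were PSAPP_CO against WT_CO, PSAPP_TAM against PSAPP_CO, WT_TAM against WT_CO, and, for the whole section and the cortex, the interaction of genotype and treatment, which is the tamoxifen effect in PSAPP minus that in WT. This made 14 comparisons and areas. Log2 fold changes are given with the standard error (SE) of the fit, and CPM as mean ± SD (n = 3). DESeq2 1.42.0 was run beside edgeR. On simulated data with 200 changed genes, the test recovered 64.2, 83.6 and 98.5% of the tested genes changed 1.5-fold, 2-fold and 4-fold in the cortex and 52.2, 66.7 and 96.9% in the whole section (35 of 67, 44 of 66 and 63 of 65). It made 11 false calls among 175 and 9 among 151, and 0 in a comparison in which nothing changed. Simulated genes varied independently of each other, without deviations of a section that many genes share. These rates therefore need not hold for the real sections.

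24 gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) in every comparison, with camera's estimated correlation and fry beside it. They covered disease-associated microglia, homeostatic microglia, plaque-induced genes, lysosome, complement, antigen presentation, interferon response, phosphoinositide and immune receptor signalling, cholesterol and lipid genes, reactive and homeostatic astrocytes, myelin, oligodendrocyte precursors, excitatory and inhibitory neurons, synapse, immediate early genes, heat shock, endothelium, mural and meningeal cells, choroid plexus, border macrophages, blood leukocytes and erythrocytes. The plaque-induced list shares members with the disease-associated, homeostatic, lysosome and complement lists. Counts of members that changed are also given "adjusted over the list alone".

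Anchor-positive spots were defined from Cst7 and Itgax, 2 genes of disease-associated microglia. A spot was positive with at least 1 UMI of either gene after it was thinned at random to 5000 UMIs (seed 7), and spots with fewer UMIs were left out. For the share of positive spots, group means were compared by exact two-sided permutation tests. With 3 against 3 sections the smallest possible p is 0.1. For the profile of positive spots in the cortex of the 6 PSAPP sections, full counts were summed per section over positive and over all other cortex spots with at least 5000 UMIs and compared in edgeR with section as a block, with the anchor genes left out. A share of 0 is given with the limit that 3 counts allow.

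The named genes follow a rule. It takes Inpp5d, Cx3cr1, App, Psen1 and Prnp in every comparison. It takes up to 10 genes per direction with the largest changes in the whole section and cortex, and up to 5 in the hippocampus and white matter, among genes with an adjusted p under 0.05, a mean of at least 5 CPM in one of both groups and no overlap between them. Where fewer than 3 genes passed, it takes the 5 genes with the smallest p as values that did not pass. It also takes 2 to 4 members with the smallest p of each list described. For anchor-positive spots it takes the 20 genes with the smallest p among those at least 1.5-fold higher and up to 5 lower genes. The groups, comparisons, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

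The alternatives were RLE size factors, no filter on low counts, spots with at least 5000 UMIs, the replicate number as a block, fits of only the 2 groups compared, each section left out in turn, clusters at resolution 1.6, sums balanced over regions, DESeq2, and for anchor-positive spots at least 2 UMIs, Cst7 alone, the cortex only, thinning to 10000 UMIs and no thinning. 3 were added after seeing the data: leaving out the spots of the Cst7-led cluster, leaving out 3 corn oil sections from another coronal plane, and leaving out Prnp. The tests in thalamus, hypothalamus, striatum, amygdala and piriform area, the comparison of PSAPP_TAM with WT_TAM and the differences between areas were also chosen after the first results were seen.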

Results

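The transcriptome of 12 coronal brain sections was measured spot by spot in mice. In these mice tamoxifen is meant to remove Inpp5d, the gene of the inositol phosphatase SHIP1, from cells that express Cx3cr1. All mice carried loxP-flanked Inpp5d and CreER, and no group received tamoxifen without Cre. An effect of tamoxifen itself and one of Inpp5d loss therefore cannot be told apart. 3 sections came from each of 4 groups: WT mice given corn oil (WT_CO) or tamoxifen (WT_TAM), and PSAPP mice, which form amyloid plaques, given corn oil (PSAPP_CO) or tamoxifen (PSAPP_TAM). Sections 1, 2 and 3 held 47.76, 69.23 and 66.37 M UMIs in WT_CO, 72.35, 96.65 and 64.68 M in WT_TAM, 74.58, 84.52 and 61.36 M in PSAPP_CO, and 86.51, 85.64 and 57.44 M in PSAPP_TAM. The cortex covered 651 to 808 spots per section, the hippocampus 225 to 351 and the white matter 218 to 285. In each section 21144 to 22361 genes were detected. WT_CO 2, WT_CO 3 and PSAPP_CO 1 held 154, 178 and 234 spots of a cluster led by Vgll3 that had at most 4 spots in any other section. They are called the 3 sections of the other coronal plane from here on.

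Inpp5d (ENSMUSG00000026288), the targeted gene, was measured at 3.83, 5.95 and 5.96 CPM in WT_CO and 8.29, 4.34 and 3.86 CPM in WT_TAM. It was measured at 8.38, 7.58 and 6.96 CPM in PSAPP_CO and 4.36, 3.98 and 4.70 CPM in PSAPP_TAM. All 3 PSAPP_TAM sections thus lay under all 3 PSAPP_CO sections. Among the WT sections, the library labelled WT_TAM 1 had the highest level and the library labelled WT_CO 1 the lowest, against the direction of their labels. The labels do not give the deleted exons, and 3′ tags outside the deleted part check nothing, so these values neither establish nor exclude a wrong label. Both libraries were kept as labelled, and every direction between WT_TAM and WT_CO rests on that. Of the genes of the transgenes, Prnp (ENSMUSG00000079037), whose reads mark the PSAPP sections, stood at 804 ± 21.9 CPM in WT_CO, 795 ± 11.3 in WT_TAM, 3279 ± 201 in PSAPP_CO and 3261 ± 21.3 in PSAPP_TAM (SD, n = 3). By this gene all 12 sections matched the genotype of their label. App (ENSMUSG00000022892), the amyloid precursor, stood at 1032 to 1082 CPM in the 4 group means, with no change called in any comparison.

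**Figure D1:**
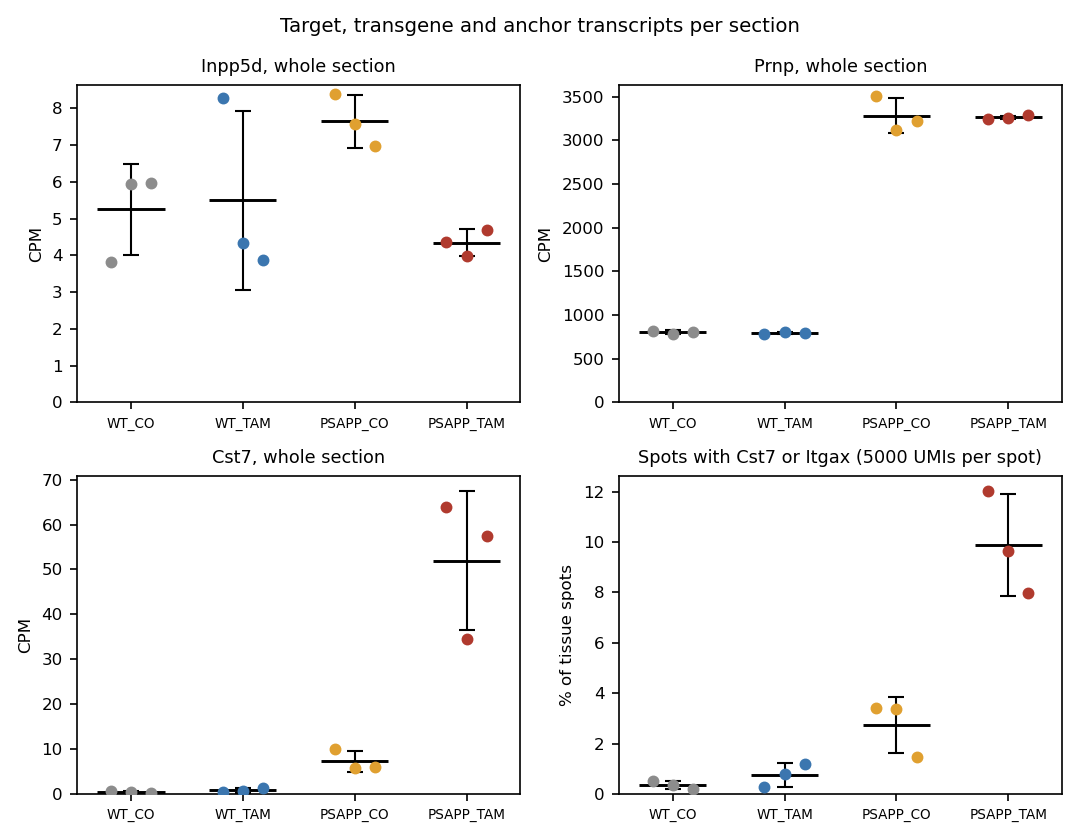
Levels of Inpp5d, Prnp and Cst7 in the whole section (CPM) and the percentage of tissue spots with a UMI of Cst7 or Itgax, for the 12 sections by group, as points with the group mean (bar) and SD (error bar, n = 3). Cst7 averaged 7.23 CPM in PSAPP_CO and 52.0 CPM in PSAPP_TAM.

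PSAPP_CO was compared with WT_CO for the effect of the amyloid transgenes where Inpp5d had not been deleted. In the cortex, Cst7 (ENSMUSG00000068129), a cystatin made by microglia near plaques, rose from 0.29 ± 0.10 to 10.2 ± 1.08 CPM, a log2 fold change of 5.18 (SE 0.44, adjusted p = 9.96e-05). Prnp rose from 795 ± 27.3 to 3895 ± 231 CPM (2.29, SE 0.09, adjusted p = 5.59e-09), and Psen1 (ENSMUSG00000019969), the presenilin of gamma-secretase, from 25.9 ± 2.54 to 38.0 ± 2.45 CPM (0.56, SE 0.08, adjusted p = 0.0472). The call of Psen1 was lost with 11 of the 12 sections left out in turn (adjusted p up to 0.193), in the fit of only the 2 groups (adjusted p = 0.295) and without Prnp. In the whole section, Cst7 rose by 4.05 (SE 0.46, adjusted p = 0.00755) and Prnp by 2.03 (SE 0.07, adjusted p = 3.37e-08). Id1, a BMP target that blocks basic helix-loop-helix factors, fell there from 29.3 ± 0.83 to 20.5 ± 0.71 CPM (-0.52, adjusted p = 0.00593). There the calls of Cst7 and Id1 ended without WT_CO 2 (adjusted p = 0.13 and 0.064), that of Cst7 without WT_CO 3 and that of Id1 in the fit of only the 2 groups and with region-balanced sums. In the hippocampus, Prnp rose by 2.0 (adjusted p = 2.24e-09) and the unannotated gene Gm49980 by 0.95 (adjusted p = 0.0211), and in the white matter Prnp alone rose, by 1.01 (adjusted p = 0.00144). The call of Gm49980 ended without any 1 of 4 sections, WT_CO 2, PSAPP_CO 1, PSAPP_CO 2 and the library labelled WT_CO 1, and at double cluster resolution. Without the 3 sections of the other plane, which leaves 1 WT_CO section, every call of this comparison ended except those of Prnp in the whole section, cortex and hippocampus, with Cst7 at 4.58 in the cortex (adjusted p = 0.138).

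Other microglial and astrocyte genes had higher values in the PSAPP_CO cortex without passing the test. Itgax, an integrin of activated microglia, had a log2 fold change of 3.62 (adjusted p = 0.243), the chemokines Ccl6 and Ccl3 1.25 (adjusted p = 0.474) and 1.72, and Gfap, the astrocyte intermediate filament, 1.23, from 18.8 ± 2.99 to 43.5 ± 5.72 CPM. Trem2, the lipid-sensing receptor of microglia, stood at 0.50, the lysozyme gene Lyz2 at 0.65 and the kinase Syk at 0.84. The lysosomal genes Ctsd and Cd68 stood at 0.32 and 0.40. These 5 genes, Ccl3 and Gfap had an adjusted p of 0.576. Inpp5d itself had a log2 fold change of 0.54 in the whole section (adjusted p = 0.701), and Cx3cr1, the fractalkine receptor, of 0.31 in the cortex.

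Of the disease-associated microglia list, 1 of 24 measured members passed the test in the cortex and 6 did when adjusted over the list alone, with a median log2 fold change of 0.35. Camera called this list with its preset correlation, but not otherwise (adjusted p = 0.159 with an estimated correlation). It also called 9 others in the cortex, none of which held with an estimated correlation: homeostatic microglia (median 0.13, adjusted p = 0.572 with an estimated correlation), plaque-induced (0.14, 0.572), lysosome (0.06, 0.572), phosphoinositide (0.14, 0.5), cholesterol (0.14, 0.5), excitatory neuron (0.08, 0.491), synapse (0.10, 0.572), immediate early (0.20, 0.662) and choroid plexus (-0.86, 0.572). In the whole section, 10 lists were called and 0 held. Among them were disease-associated microglia (median 0.16, 2 members adjusted over the list alone) and homeostatic microglia (0.20, 4 members), both with an adjusted p = 0.239 with an estimated correlation, and border macrophages (-0.38, adjusted p = 0.111 with an estimated correlation). In the hippocampus, the synapse and cholesterol lists were among 6 called, at medians of 0.20 and 0.21 (adjusted p = 0.459 with an estimated correlation for both), and in the white matter the heat shock list at -0.18 (adjusted p = 0.961).

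The edgeR quasi-likelihood test called 3 of 17993 genes in the whole section, 3 of 15649 in the cortex, 2 of 13695 in the hippocampus and 1 of 11651 in the white matter. At an unadjusted p under 0.05 there were 1271, 1344, 929 and 473 genes, and DESeq2 called 19, 6, 4 and 2. Without the filter on low counts 5, 89 and 29 genes were called in the cortex, hippocampus and white matter. With the replicate block these counts were 6, 8 and 2, and the whole-section count stayed at 3 in both fits.

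PSAPP_TAM was compared with PSAPP_CO for what tamoxifen, given to delete microglial Inpp5d, changes in a plaque-forming brain. In the cortex, most measured members of the disease-associated microglia, lysosome, complement and interferon lists rose. Cst7 rose from 10.2 ± 1.08 to 86.7 ± 26.9 CPM (log2 fold change 3.07, SE 0.22, adjusted p = 6.86e-06). Ifi27l2a (ENSMUSG00000079017), an interferon-induced gene, rose from 3.68 ± 0.30 to 54.4 ± 15.4 CPM (3.89, SE 0.27, adjusted p = 6.86e-06). Trem2 (ENSMUSG00000023992) rose from 29.3 ± 2.15 to 90.9 ± 17.9 CPM (1.63, SE 0.15, adjusted p = 5e-05), and Tyrobp (ENSMUSG00000030579), the adaptor through which TREM2 signals, from 91.5 ± 10.3 to 354 ± 67.1 CPM (1.95, SE 0.19, adjusted p = 7.13e-05). Inpp5d had a log2 fold change of -0.83 (SE 0.20, adjusted p = 0.0586), from 8.73 ± 1.08 to 4.94 ± 0.38 CPM, with the 3 tamoxifen sections under the 3 corn oil sections. Over the alternatives its adjusted p was 0.00759 to 0.377. It passed with DESeq2 (adjusted p = 0.00759), without the filter on low counts, with the replicate block, in the fit of only the 2 groups, and without WT_TAM 3 or the library labelled WT_TAM 1.

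The other largest rises in the cortex were those of the chemokine genes Ccl12 (2.69), Ccl4 (2.51), Ccl3 (2.50) and Ccl6 (2.15), which attract monocytes and other leukocytes, and of Cd52 (2.37), a short surface glycoprotein of leukocytes. Lgals3bp, a secreted galectin-binding protein induced by interferon, rose by 2.36, Cd74, the invariant chain of MHC class II, by 2.20, and Lyz2 by 2.17. Only 7 genes fell. The 5 named by the rule were Asic4 (-0.71), an ion channel gene, Prkca (-0.41), the gene of protein kinase C alpha, Myo1b (-0.40), an unconventional myosin, Fam160b2 (-0.35) and Peli3 (-0.33), a ubiquitin ligase of innate immune signalling. Cx3cr1 rose from 8.01 ± 1.08 to 13.5 ± 1.98 CPM (0.75, adjusted p = 0.00432).

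Of the disease-associated microglia list, 17 of 24 measured members rose in the cortex and 7 did not pass, while 22 rose when adjusted over the list alone, with a median of 1.25 (adjusted p = 0.000893 with an estimated correlation). Apoe, the main brain apolipoprotein and a member of that list, did not pass (0.27, adjusted p = 0.382). Of the homeostatic microglia list, 9 of 13 rose (12 adjusted over the list alone, median 0.75, adjusted p = 0.00218 with an estimated correlation), among them Siglech (1.14), Fcrls (1.29), Selplg (0.96) and Csf1r (0.80), the receptor microglia need to survive. Of the plaque-induced list, 42 of 53 rose (49 adjusted over the list alone, median 1.0). Of the lysosome list, 16 of 24 rose (20 adjusted over the list alone, median 0.62), among them the cathepsin genes Ctsd, from 342 ± 16.2 to 782 ± 156 CPM (1.2), Ctsz (1.31) and Ctss (1.53), and Cd68 (1.47). Of the complement list, 9 of 12 rose (11 adjusted over the list alone, median 1.62), with the chains of C1q, C1qa (1.67), C1qb (1.61) and C1qc (1.67), and the receptor C3ar1 (1.63).

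Of the interferon list, 15 of 19 rose (19 adjusted over the list alone, median 1.73), among them Bst2 (2.12), which tethers enveloped virions, and Rtp4 (1.48). Of the antigen presentation list, 8 of 12 rose (10 adjusted over the list alone, median 1.26), with the class I genes H2-D1 (1.34) and H2-K1 (1.45) and the immunoproteasome subunit Psmb8 (1.41). Of the phosphoinositide and immune receptor list, which holds Inpp5d, 13 of 20 rose (median 1.02), and when adjusted over the list alone 13 rose and Inpp5d fell. The members named, Tyrobp, Trem2, Fcer1g (1.5), the signalling chain of Fc receptors, and Fcgr2b (1.46), the inhibitory Fc receptor, are immune receptors and adaptors, not phosphoinositide enzymes. The plaque-induced, lysosome, complement, interferon, antigen presentation and phosphoinositide lists all kept their call, at an adjusted p of 0.00127 with an estimated correlation.

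Lists of other cell types held few called genes in the cortex. Of the reactive astrocyte list, 2 of 14 rose, Serpina3n (1.34, adjusted p = 0.0238), a secreted protease inhibitor, and S100a6 (0.79), and 5 rose when adjusted over the list alone (median 0.64, adjusted p = 0.1 with an estimated correlation). Gfap stood at 43.5 ± 5.72 and 123 ± 92.9 CPM, a log2 fold change of 1.51 that did not pass (adjusted p = 0.0508), and Vim at 1.46. Of the cholesterol list only Ch25h, which makes 25-hydroxycholesterol, rose, by 2.28 (median 0.12, adjusted p = 0.297 with an estimated correlation). The heat shock list (median 0.11) and the choroid plexus list (-1.51) were called with the preset correlation (adjusted p = 0.324 with an estimated correlation for both), with 0 members passing, and 2 heat shock members adjusted over the list alone. Camera called none of the homeostatic astrocyte (median 0.00), myelin (-0.07), oligodendrocyte precursor (-0.04), excitatory neuron (-0.03), inhibitory neuron (-0.05), synapse (-0.02), immediate early (0.17), endothelial (0.05), mural and meningeal (-0.03), border macrophage (0.44), blood leukocyte (0.12) and erythrocyte (0.01) lists, and no member of these passed over all genes.

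**Figure D2:**
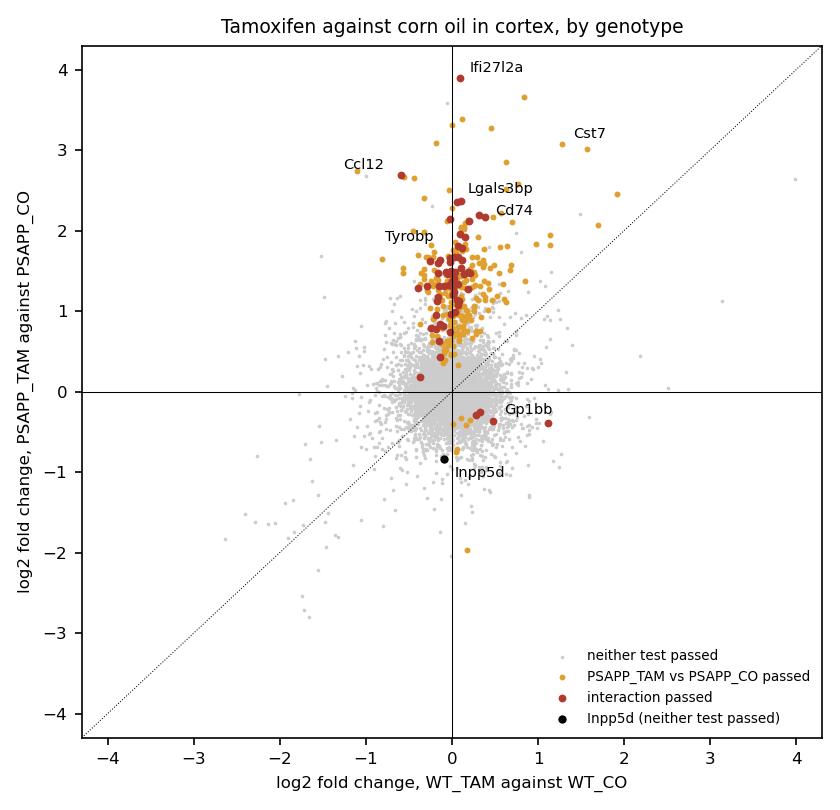
Log2 fold change of tamoxifen against corn oil in the cortex of WT (horizontal axis) and PSAPP sections (vertical axis), 1 point per gene tested, in grey where neither test passed, orange where the PSAPP test passed and red where the interaction passed, with Inpp5d in black and a dotted line at equal changes. Ifi27l2a and Cst7 lie at 3.89 and 3.07 on the vertical axis.

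In the hippocampus, 186 genes rose and 34 fell. Ifi27l2a rose from 2.97 ± 0.53 to 49.4 ± 18.6 CPM (4.02, SE 0.26, adjusted p = 1.49e-07), Cst7 from 4.77 ± 2.65 to 83.3 ± 27.1 CPM (3.98, adjusted p = 1.56e-07) and Cd52 from 6.83 ± 0.94 to 67.2 ± 5.75 CPM (3.27, adjusted p = 1.69e-07). Ccl3 rose by 2.95, and Col6a1, a chain of collagen VI, by 3.15, with 23.2 ± 16 CPM in PSAPP_TAM. The largest falls were those of the desmosome gene Dsp, from 29.7 ± 7.26 to 7.97 ± 8.22 CPM (-2.22, adjusted p = 0.00209), Tdo2 (-1.77), which degrades tryptophan, Ryr1 (-1.53), a calcium release channel, the transporter-family gene Slc26a10 (-1.3) and Calb1 (-1.05), the calcium buffer calbindin, from 111 ± 11.3 to 55.3 ± 24.4 CPM. Dsp and Slc26a10 were among the genes that led the hippocampal cluster led by C1ql2, which marks dentate granule cells, and this cluster held 95, 88 and 74 spots in PSAPP_CO and 128, 108 and 84 in PSAPP_TAM. C1ql2 (0.41, adjusted p = 0.0984), Prox1 (-0.32) and Lct (-0.19), markers of the same spots chosen after their values were seen, did not pass, though C1ql2 did with the replicate block (adjusted p = 0.0204).

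By list, 19 of 24 disease-associated members rose in the hippocampus (20 adjusted over the list alone, median 1.55), 7 of 13 homeostatic (12, median 0.73), 42 of 53 plaque-induced (46, median 1.09) and 16 of 24 lysosome members (19, median 0.67). So did 8 of 11 complement (11, median 1.5), 8 of 12 antigen presentation (12, median 1.21), 6 of 15 interferon (15, median 1.28; 10 with the replicate block) and 7 of 18 phosphoinositide members (11, median 1.01). All 8 lists kept their call, at adjusted p of 0.00014 to 0.00199 with an estimated correlation. Examples were Trem2 (1.76), Tyrobp (2.09), C1qb (1.71), Itgb2 (2.04), an integrin chain of complement receptors, and B2m (1.16), the light chain of MHC class I. 4 of 13 reactive astrocyte genes rose: Gfap (1.52, adjusted p = 0.00404), S100a6 (1.60), Vim (1.32) and Serpina3n (0.86), though the list's call was lost (adjusted p = 0.0828 with an estimated correlation). Gfap varied widely between the PSAPP_TAM sections, at 336 ± 220 CPM. Calls of the cholesterol (median 0.20, adjusted p = 0.107), heat shock (0.23, 0.209), choroid plexus (-0.85, 0.385) and erythrocyte (-0.81, 0.43) lists were also lost with an estimated correlation.

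In the whole section the same lists rose, with smaller medians than in the cortex: 14 of 24 disease-associated members (21 adjusted over the list alone, median 0.90), 35 of 53 plaque-induced (47, median 0.71), 12 of 24 lysosome (18, median 0.40) and 8 of 12 complement (10, median 0.96). So did 9 interferon (16, median 1.25), 5 homeostatic (9, median 0.50), 4 antigen presentation (9, median 0.71) and 11 phosphoinositide members (13 up and Inpp5d down, median 0.69), each with an adjusted p of 0.00256 or less with an estimated correlation. Here the reactive astrocyte list was called as well, with S100a6 (0.95), Serpina3n (1.24) and Vim (1.03) rising and 8 members adjusted over the list alone (median 0.43, adjusted p = 0.00886 with an estimated correlation). The border macrophage (0.44) and blood leukocyte (0.76) lists were called without a member passing over all genes (adjusted p = 0.00539 and 0.0203 with an estimated correlation), while those of the heat shock (0.176), cholesterol (0.305) and mural (0.531) lists were lost. The largest single rises were Cst7 (2.84), Ifi27l2a (2.45), Ccl12 (2.38), Ccl3 (2.05), Cd52 (2.04), Ccl6 (1.63), the ubiquitin-like interferon effector Isg15 (1.57), Ccl9 (1.52), Lyz2 (1.52) and Tyrobp (1.49). Dlx6os1, a long RNA of forebrain interneurons, fell by 0.36 (adjusted p = 0.0312), and Inpp5d had a log2 fold change of -0.82 (adjusted p = 0.288). Over the alternatives its adjusted p there was 0.0165 to 0.817, and it passed in the fit of only the 2 groups and without the library labelled WT_TAM 1.

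In the white matter no gene passed edgeR's test, with 473 of 11651 at an unadjusted p under 0.05 and 2 called by DESeq2. This 0 depended on the fit. Without the filter on low counts 39 genes were called, with the replicate block 25 and from only the 2 groups 13. The smallest p-values were those of Serpina3n (1.78, from 26.0 ± 10.5 to 87.8 ± 8.23 CPM, adjusted p = 0.113), Vim (1.04, adjusted p = 0.272), C1qc (0.63), Trem2 (0.60) and S100a4 (1.47), the last 3 with an adjusted p of 0.281. Several lists were nevertheless called. Adjusted over the list alone, 14 of 23 disease-associated members rose (median 0.60, adjusted p = 0.0286 with an estimated correlation), 29 of 52 plaque-induced (0.39, 0.0197), 9 of 24 lysosome (0.23, 0.0286), 5 of 11 complement (0.51, 0.0286), 6 of 14 reactive astrocyte (0.57, 0.0311) and 3 of 8 heat shock members (0.39, 0.0286). Of the phosphoinositide list 4 of 16 rose and Inpp5d fell (0.31, 0.0197). Calls of the homeostatic (adjusted p = 0.264), antigen presentation (0.175), interferon (0.606), cholesterol (0.204), mural (0.24) and erythrocyte (0.159) lists were lost with an estimated correlation. The interferon list had a median of -0.05 but a mean of 0.07 and an upward call.

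**Figure D3:**
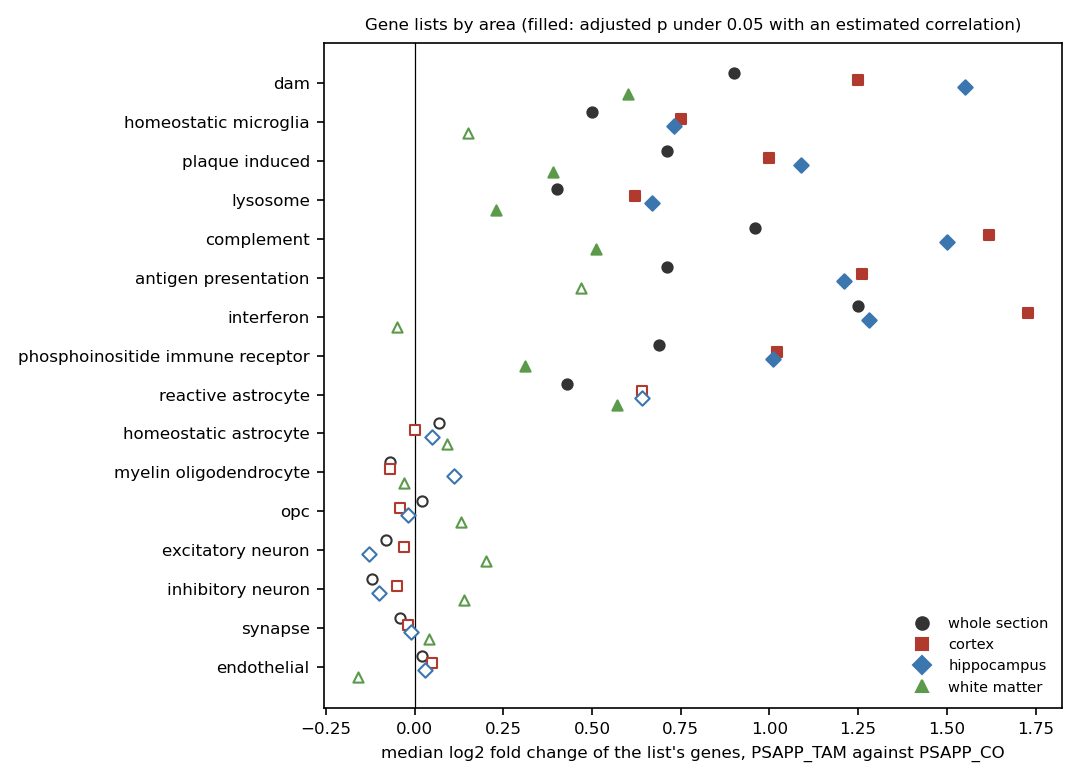
Median log2 fold change (horizontal axis) of 16 gene lists in PSAPP_TAM against PSAPP_CO, in the whole section, cortex, hippocampus and white matter, with filled points for an adjusted p under 0.05 with an estimated correlation. The disease-associated list (dam; opc marks oligodendrocyte precursors) lies at 0.90, 1.25, 1.55 and 0.60.

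The quasi-likelihood test called 191 genes in the whole section (186 higher, 5 lower), 278 in the cortex (271 and 7) and 220 in the hippocampus (358 with the replicate block), and DESeq2 called 317 in the whole section. All 191 and all 278 separated both groups without overlap, and 219 of 220 in the hippocampus, where chance alone separates 10% of genes and 13.88, 14 and 13.54% of all genes were separated. Without the 3 sections of the other plane the counts were 126, 185 and 115, and the lowest counts with 1 section left out, PSAPP_TAM 1 in each area, were 84, 170 and 118. Without the spots of the Cst7-led cluster, of which the PSAPP_TAM sections held 83, 55 and 48 and the PSAPP_CO sections 8, 7 and 6, the cortex count was 87 and the hippocampus count 104.

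WT_TAM was compared with WT_CO for the effect of tamoxifen, given to delete Inpp5d, without amyloid transgenes. No gene passed edgeR's test in the whole section, the cortex or the white matter, and 1 did in the hippocampus: Gm49980 rose from 32.9 ± 8.5 to 64.0 ± 7.42 CPM (1.0, SE 0.14, adjusted p = 0.0225). The values behind this comparison include the libraries labelled WT_TAM 1 and WT_CO 1. Inpp5d had log2 fold changes of 0.07 in the whole section (adjusted p = 0.98) and -0.09 in the cortex. Without the library labelled WT_TAM 1 these were -0.363 and -0.378, and -0.833 in the hippocampus, where the value over all sections was -0.076. None of these passed. Without the 3 sections of the other plane the log2 fold changes in these 3 areas were 0.525, 0.129 and 1.536. That fit leaves in WT_CO only the library labelled WT_CO 1, whose Inpp5d level goes against its label. These 3 values therefore rest on that library. Cx3cr1 stood at 7.49 ± 1.36 and 8.60 ± 0.59 CPM. The disease-associated list had a median of 0.00 in the whole section.

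The genes with the smallest p-values were Xlr4b (-2.37, adjusted p = 0.372), Tnni3 (-1.14), Id1 (-0.32), Barhl1 (-4.62) and Gsn (-0.34) in the whole section. In the cortex they were CAAA01066123.1 (1.11, adjusted p = 0.46), the layer 5 transcription factor gene Fezf2 (-0.37), the stress peptide gene Crh (-0.45), the astrocyte connexin gene Gjb6 (-0.43) and the interneuron peptide gene Vip (-0.57). In the white matter they were Nefh (1.10), a neurofilament gene, Polr3e (-1.01), Pwwp2b (1.81), Lpl (1.82), the lipoprotein lipase gene, and Tprn (-0.52), all with an adjusted p of 0.348. Choroid plexus genes had lower values in WT_TAM: 10 of 10 fell when adjusted over the list alone, in the whole section (median -2.17, adjusted p = 0.43 with an estimated correlation) and in the cortex (-1.84, adjusted p = 0.624). With the replicate block camera also called the synapse list in the whole section (adjusted p = 0.033, 0.832 with an estimated correlation). The myelin list had medians of -0.24 in the whole section and -0.30 in the white matter (adjusted p = 0.682 and 0.499 with an estimated correlation). In the hippocampus, camera called the disease-associated (median 0.24), plaque-induced (0.26), complement (0.30), interferon (0.44) and myelin (0.33) lists among others, and none held (adjusted p = 0.202 for the first and 0.199 for the other 4 with an estimated correlation).

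At an unadjusted p under 0.05 there were 1001 genes in the whole section, 679 in the cortex, 802 in the hippocampus and 915 in the white matter, and DESeq2 called 10 in the whole section, 1 in the cortex, 1 in the hippocampus and 0 in the white matter. Without the filter on low counts 56 genes were called in the hippocampus and 110 in the white matter. With the replicate block 129 were called in the white matter, where the pairs correlated at 0.115, 0.058 and 0.23. The call of Gm49980 ended without any 1 of 4 sections: WT_CO 2, WT_TAM 3 and the libraries labelled WT_CO 1 and WT_TAM 1. It also ended at double cluster resolution and without the 3 sections of the other plane.

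The interaction asked whether tamoxifen acted differently in PSAPP and in WT sections. In the cortex, 62 genes differed: 58 had a larger rise in PSAPP and 4 a lower effect there. Ifi27l2a differed by 3.8 log2 units (SE 0.44, adjusted p = 0.00276): its mean in WT was 3.62 CPM with corn oil and 3.76 with tamoxifen, against 3.68 and 54.4 in PSAPP. Lgals3bp differed by 2.30 (SE 0.25, adjusted p = 0.00276), Ccl12 by 3.28 and Cd52 by 2.26. Ccl6 differed by 2.17, Bst2 by 1.92, Cd74 by 1.89, Tyrobp by 1.86, Lyz2 by 1.79 and C3ar1 by 1.77. Ctsz, Trem2 and C1qa differed by 1.46, 1.52 and 1.60. In the whole section 4 genes differed, Ccl3 (2.70, adjusted p = 0.0246), Cd68 (1.16, adjusted p = 0.015), Cyba (1.13), a subunit of the phagocyte NADPH oxidase, and Ctsz (1.01). All 4 of these calls ended without any 1 of 6 sections: WT_CO 2, PSAPP_CO 2, PSAPP_CO 3, PSAPP_TAM 1, PSAPP_TAM 3 and the library labelled WT_CO 1.

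The genes with lower effects in PSAPP were Gp1bb (-0.84, adjusted p = 0.0407), Rasd2 (-0.58), a small G protein of neurons, Cacna1i (-0.57), a T-type calcium channel, and CAAA01066123.1. Gp1bb stood at 8.80 and 12.3 CPM in WT_CO and WT_TAM and at 12.3 and 9.60 CPM in PSAPP_CO and PSAPP_TAM. By list, 8 of 24 disease-associated members differed in the cortex (17 adjusted over the list alone, median 1.14, adjusted p = 0.00938 with an estimated correlation), 20 of 53 plaque-induced (46, median 0.98), 9 of 24 lysosome (19, median 0.60) and 6 of 12 complement members (10, median 1.61). So did 5 of 19 interferon (13, median 1.35), 3 of 12 antigen presentation (7, median 1.07), 4 of 20 phosphoinositide (11 up, Inpp5d down, median 0.85) and 2 of 13 homeostatic members (12, median 0.68). These 8 lists kept their call with an estimated correlation, at adjusted p up to 0.0132, while the reactive astrocyte call (median 0.71) was lost (adjusted p = 0.2). In the whole section 16 lists were called and 11 held, the reactive astrocyte list among them (median 0.64, 8 members adjusted over the list alone, adjusted p = 0.0137). Inpp5d did not pass (-0.75 in the cortex, adjusted p = 0.4).

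At an unadjusted p under 0.05 there were 1561 genes in the cortex and 1289 in the whole section. The whole-section count of 4 was 29 without the filter on low counts, 13 with the replicate block and 37 with region-balanced sums. It was higher still with DESeq2. With the replicate block the cortex count of 62 was 453. In neither area did all pairs of sections exceed a correlation of 0.1 in both genotypes. The cortex count was 4 without the 3 sections of the other plane, 2 without the spots of the Cst7-led cluster, 31 without the library labelled WT_CO 1, 41 without the library labelled WT_TAM 1, 30 without PSAPP_CO 1, 34 without PSAPP_TAM 1, 40 without PSAPP_CO 2, 132 without the filter on low counts, and 184 with DESeq2.

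Spots with a UMI of Cst7 or Itgax were counted to ask where in the tissue this microglial state appeared. With every spot thinned to 5000 UMIs, they made up 0.357 ± 0.157% of spots in WT_CO, 0.747 ± 0.462% in WT_TAM, 2.748 ± 1.11% in PSAPP_CO and 9.888 ± 2.029% in PSAPP_TAM (SD, n = 3). The PSAPP_TAM sections held 12.03, 9.638 and 7.996% and the PSAPP_CO sections 3.414, 3.362 and 1.466%. Tamoxifen sections exceeded corn oil sections by 7.14 points in PSAPP (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3) and by 0.39 points in WT (exact p = 0.3). The latter was 0.634 without the library labelled WT_TAM 1 and 0.176 without WT_TAM 3, and its direction rests on the labels of WT_TAM 1 and WT_CO 1. PSAPP exceeded WT by 5.766 points within treatment (exact p = 0.005, the smallest of 400 labelings).

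By region, which was not tested, the mean shares in PSAPP_CO and PSAPP_TAM were farthest apart in the meninges and vessels, at 6.02 and 21.74%, and in the cortex, at 3.87 and 15.58%. They were 3.01 and 11.72% in the hippocampus, 5.56 and 12.87% in the amygdala and piriform area, 1.99 and 8.46% in the white matter, 1.70 and 3.65% in the striatum, 0.14 and 3.17% in the hypothalamus and 0.51 and 4.46% in the ventricle and choroid plexus. The thalamus held 0 positive of 978 spots in PSAPP_CO, which allows a share of up to 0.307%, and the habenula 0 of 51, which allows up to 5.882%, against 1.71 and 1.89% in PSAPP_TAM. The habenula share in PSAPP_TAM rested on 2 positive of 115 spots. WT sections held such spots as well, in WT_CO and WT_TAM 0.98 and 2.81% in the habenula and 0.51 and 0.71% in the thalamus. In the white matter they held 2.03% in WT_CO and 4.22 ± 3.20% in WT_TAM. White matter shares rested on 484, 361, 646 and 645 spots with at least 5000 UMIs in WT_CO, WT_TAM, PSAPP_CO and PSAPP_TAM.

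**Figure D4:**
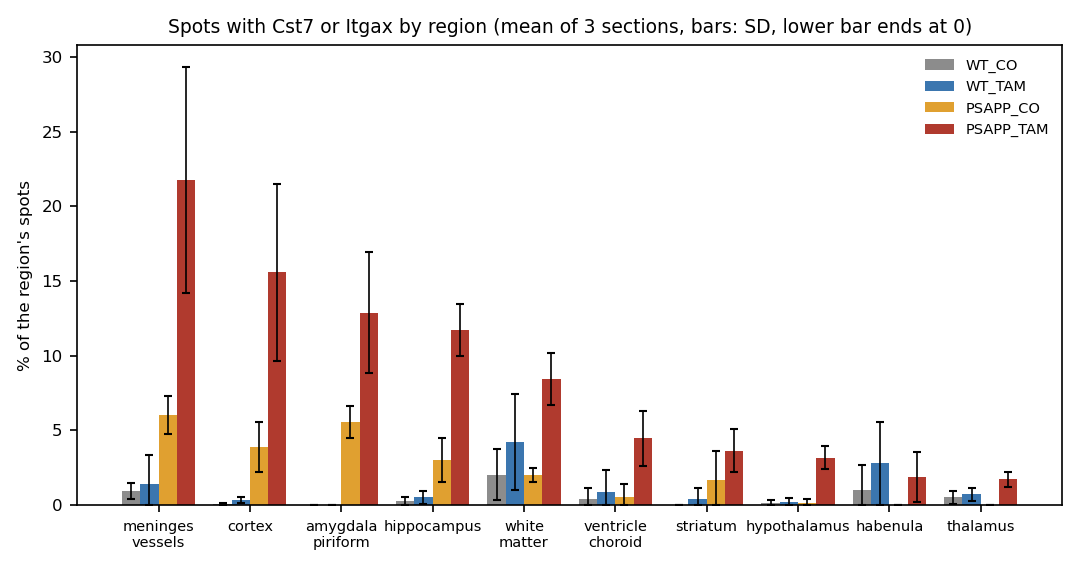
Percentage of spots with a UMI of Cst7 or Itgax after thinning to 5000 UMIs, by region and group, with bars for means of 3 sections and error bars for the SD, drawn no lower than 0. The cortex of PSAPP_TAM reached 15.58% and that of PSAPP_CO 3.87%.

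In the cortex of the 6 PSAPP sections, anchor-positive spots, 37, 31 and 13 in PSAPP_CO and 179, 96 and 79 in PSAPP_TAM, were compared with the other cortex spots of the same section that had at least 5000 UMIs. Of these 3870 other spots, 828 (21.4%) held a UMI of either gene at full depth, 84, 85 and 51 in PSAPP_CO and 296, 186 and 126 in PSAPP_TAM, so both classes overlap, and more so in PSAPP_TAM. Lyz2 was higher there by 2.97 log2 units (SE 0.10, adjusted p = 7.07e-17), Tyrobp by 2.77, Trem2 by 2.51 and Cd52 by 2.44, each in 6 of 6 sections. The other genes named by the rule were, among chemokines, Ccl3 (3.81) and Ccl6 (3.23) and, among complement genes, C1qc (1.99) and C1qa (1.93). Among lysosomal genes they were Cd68 (2.54), Ctsd (2.04), Ctsz (2.02), Ctss (1.93), Ctsh (1.83), Hexb (1.64), a subunit of beta-hexosaminidase, and Laptm5 (1.74). The rest were Mpeg1 (2.51), a pore-forming protein of macrophages, Fcer1g (2.01), Lgals3bp (2.0), Fcrls (1.99) and Cyba (1.97). All were higher in 6 of 6 sections. Lower in positive spots were the layer 6 genes Nr4a2 (-0.63), Cplx3 (-0.96) and Nxph3 (-0.72), the small heat shock gene Cryab (-0.39) and Igsf21 (-0.42).

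By list, 21 of 22 disease-associated members were higher in positive spots (median 2.03), 13 of 13 homeostatic (1.21), 49 of 52 plaque-induced (1.47) and 21 of 24 lysosome members (1.18). So were 10 of 11 complement (1.73), 11 of 12 antigen presentation (1.38), 11 of 17 interferon (0.87) and 13 of 19 phosphoinositide members (1.46). Adjusted over the list alone these counts were 21, 13, 51, 21, 10, 12, 15 and 13. Of the myelin list, 7 of 12 were lower and 10 adjusted over the list alone (median -0.30). Positive and other spots were not matched for cortical layer. Whether layer accounts for the lower myelin and layer 6 genes was not tested. Of the reactive astrocyte list, 6 of 12 were higher and 1 lower (median 0.34). Of the cholesterol list, 4 of 17 were higher (5 adjusted over the list alone, median 0.01). No synapse, endothelial, homeostatic astrocyte or heat shock gene differed. The contrast between positive and other spots differed with treatment for 26 genes (978 at an unadjusted p under 0.05, 17 with DESeq2). It was larger in PSAPP_TAM for Ctsz (0.73, adjusted p = 0.0064) and C1qa (0.68, adjusted p = 0.0489), and lower for Cplx3 (-1.09) and Nxph3 (-0.91). Neither the uneven overlap of the classes nor cortical layer was corrected for.

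**Figure D5:**
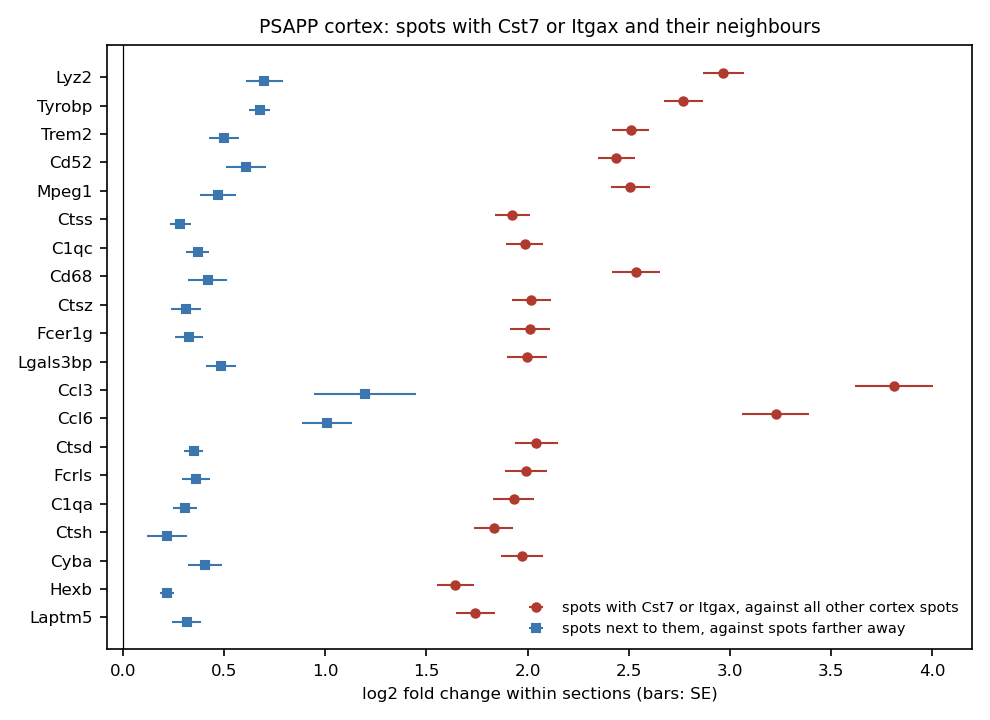
Log2 fold change ± SE of 20 genes in anchor-positive against other cortex spots (red) and in spots adjacent to positive spots against farther spots (blue), over 6 PSAPP sections. Lyz2 lies at 2.97 in positive spots and 0.70 in adjacent spots.

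Over 14046 genes tested, 639 were higher and 87 lower in positive spots. Of the 639, 420 were at least 1.5-fold higher and 394 were higher in all 6 sections. With at least 2 UMIs required the count of higher genes was 984. The count by treatment was 6 without PSAPP_CO 2, 16 without PSAPP_CO 1 and 46 without PSAPP_CO 3.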

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

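The tests of section plane and of RNA make-up behind the cortical rise, the differences between areas, and the counts over other splits of the sections for the first 14 comparisons and areas were chosen only after the result was seen.

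The tamoxifen effect differed between PSAPP and WT sections, by the interaction test, for 62 genes in the cortex and 4 in the whole section, and for 10 and 16 gene lists with the preset correlation. In the cortex the log2 differences were 3.8 for Ifi27l2a, 3.28 for Ccl12, 2.3 for Lgals3bp, 2.26 for Cd52, 2.17 for Ccl6, 1.92 for Bst2, 1.89 for Cd74, 1.86 for Tyrobp, 1.79 for Lyz2 and 1.77 for C3ar1, all rising more in PSAPP, and -0.84 for Gp1bb, -0.58 for Rasd2 and -0.57 for Cacna1i. In the whole section they were 2.7 for Ccl3, 1.16 for Cd68, 1.13 for Cyba and 1.01 for Ctsz. Of 100 splits of the sections, 8 gave as many genes as the 62 in the cortex, with a highest other count of 159. For the whole section, 6 gave as many as the 4, with a highest other count of 146. Chance was not excluded as the source of these counts. Both counts include the real split. Of the other 99 splits, 9 left the PSAPP sections in their own groups and moved only WT sections, and these gave 56 to 159 genes in the cortex, while the other 90 gave at most 2. The count therefore rested on the treatment effect in PSAPP, and how the WT sections were divided changed it little or raised it. The libraries labelled WT_TAM 1 and WT_CO 1 enter this test, and the cortex count was 41 without the former and 31 without the latter.

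Inpp5d pointed against the labels of those libraries, at 8.29 CPM in WT_TAM 1 and 3.83 CPM in WT_CO 1, where the other WT_TAM sections had 4.34 and 3.86 CPM and the other WT_CO sections 5.95 and 5.96 CPM. The share of anchor-positive spots, 0.257% in WT_TAM 1 and 0.509% in WT_CO 1, was likewise the lowest of the WT_TAM sections (0.809 and 1.174% in the others) and the highest of the WT_CO sections (0.368 and 0.195% in the others). No other measure in the files identifies treatment in WT sections, so neither the labels nor an exchange was tested, and WT_TAM against WT_CO stayed at 0 genes in the whole section and cortex without either library.

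Area differences were tested because the treatment effect in PSAPP was called in some areas only. 36 of 15102 genes had a lower log2 fold change in the white matter than in the cortex, among them Ifi27l2a (-3.25), Mpeg1 (-1.53), Tyrobp (-1.3), C1qb (-1.08) and Trem2 (-1.0). Over the 202 genes called higher in the cortex and tested in both areas, the starting level was 12.61 CPM in the white matter and 4.52 CPM in the cortex. A lower log2 fold change there need not be a smaller rise in CPM. For 15 of 15212 genes the tamoxifen effect in PSAPP differed between hippocampus and cortex. This effect was lower in the hippocampus for Calb1 (-1.01) and 3 others. It was higher there for 11 genes, among them Col6a1 (2.96), Grp (2.20), Igfbp6 (2.13), Drd1 (1.54) and Rprm (1.26). 783 and 999 genes had an unadjusted p under 0.05. For each, 10 splits are too few for a share under 0.05. The real split gave the highest count (1 of 10 in both), 36 against 0 and 15 against 3 in the highest other split.

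The second matrix of WT_TAM 2 covered the whole array, with 2.51% of its UMIs, 2491097, in 1866 spots off the tissue, a signal in data that no comparison used. These spots had a median of 657.5 UMIs against 28875.5 on the tissue, 2921 in the 225 spots next to it and 619 farther away. Across genes, which are not independent replicates, their profile correlated with that of the tissue at r = 0.989, and they held 0 of the 117 anchor UMIs.

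Weighing the rise of 271 genes in the PSAPP_TAM cortex, the values argue against a difference in depth. They also argue against more microglial RNA of unchanged make-up as the only source. With every cortex thinned to the lowest total, 14.49 M UMIs, 217 genes were called, 216 of them higher. The plane of the section was not decided. Without the 3 sections of the other plane, the median log2 fold change of these genes was 1.29, or 97.9% of the 1.31 over all sections. Only PSAPP_CO 1 of those sections enters this comparison. The genes were chosen in the same fit and separated both groups without overlap, so a large fall could hardly have occurred. More microglial RNA of unchanged make-up would raise both microglial lists alike, but the disease-associated list rose over the homeostatic list by 0.56 log2 units, 9.3 times the SD of 0.06 within groups. That difference was 0.70, 0.72 and 0.84 in PSAPP_CO and 1.35, 1.3 and 1.28 in PSAPP_TAM. The homeostatic list rose too. Its mean log2 CPM was 4.09, 4.14 and 3.98 in PSAPP_CO and 5, 4.67 and 4.76 in PSAPP_TAM. Part of the rise was thus common to both lists. As a hypothesis from these data, tamoxifen treatment of PSAPP mice may shift microglial RNA toward the disease-associated lists, and how far more microglia, more plaque or a changed state per cell add to it stays open. That this needs amyloid was not shown: in WT_TAM against WT_CO, Inpp5d had log2 fold changes of 0.07 in the whole section and -0.09 in the cortex, and without the library labelled WT_TAM 1 these were -0.363 and -0.378. None passed, so whether Inpp5d fell without amyloid stays open.

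The absence of calls in the white matter belonged to the main fit. Without the filter on low counts 39 genes were called, with the replicate block 25 and from only the 2 groups 13. Weighing the absence for the main fit, no technical source was excluded. With each cortex thinned to the total of the section's white matter, 1.15 to 3.17 M UMIs, 69 genes were still called, fewer than the 278 at full depth and between the limits set in advance, so depth could account for part of the absence. Over the 202 genes called higher in the cortex and tested in both areas, the median rise in CPM in the white matter was 72% of that in the cortex, 3.67 against 5.1 CPM, from starting levels of 12.61 and 4.52 CPM. A like rise over a higher starting level and a smaller response cannot be told apart by this value, which also fell between the limits. 180 of the 202 genes had a log2 fold change above 0 in the white matter.

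For the lower choroid plexus genes in WT_TAM (median -2.17), the median was -1.73 with the spots of the ventricle and choroid plexus clusters left out. Counts from those spots were therefore not the whole source. Plexus transcripts counted in other spots were not removed, so the amount of plexus in a section was not excluded. Those clusters held 23, 81 and 78 spots in WT_CO and 31, 40 and 14 in WT_TAM. Without the 3 sections of the other plane the median was -0.89. That test leaves 1 WT_CO section, the library labelled WT_CO 1, so plane and treatment cannot be told apart, and no biological explanation was tested.

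For the other comparisons, 3 against 3 sections make 10 splits, too few for a share under 0.05. PSAPP_TAM against PSAPP_CO gave 191 genes in the whole section (1 of 10 splits as large) against 0 in the highest other split, 278 against 0 in the cortex (1), 220 against 2 in the hippocampus (1) and 0 against 1 in the white matter (10). PSAPP_CO against WT_CO gave 3 against 0 in the cortex (1), 2 against 0 in the hippocampus (1), 1 against 0 in the white matter (1) and 3 against 130 in the whole section (2). The split with 130 genes set WT_CO 2, WT_CO 3 and PSAPP_CO 1 apart, which points to the plane of the section as a structure of the samples, and without these sections this comparison gave 4 genes, of which only Prnp was among the 3 called over all sections. WT_TAM against WT_CO gave 0 against 0 in the whole section, cortex and white matter (10 each) and 1 against 1 in the hippocampus (2). For anchor-positive spots, 32 ways of swapping both spot classes within sections were counted: 1 gave 639 genes, the real one, and the highest other 447. Because positive spots were chosen by UMIs of 2 microglial genes, a high count of microglial genes is in part built into this test. It therefore does not exclude chance for single genes. The difference of these spots by treatment gave 26 genes against 23 in the highest other split (1 of 10).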

How the results depend on the processing

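3 of the alternatives, leaving out the Cst7-led cluster, leaving out the 3 sections of the other plane and leaving out Prnp, were tests chosen only after the result was seen. So were the pairing checks in the hippocampus and white matter. Of 3523 pairs of a called gene named here and an alternative, 3162 kept the call with its direction, 361 lost it and 0 reversed. Of 2045 pairs of a named gene without a call and an alternative, 74 gained a call: 21 without the filter on low counts, 15 with the replicate block, 13 with DESeq2 and 25 with others. Among counts and shares, 315 values were labelled the same and 106 moved. Counts were the same within 1.5 times the reported count. Shares were the same where the permutation p stayed on its side of 0.05. With 3 against 3 sections the smallest possible permutation p is 0.1. For those shares the label therefore says nothing about how far the value moved. No count moved beyond 1.5 times with RLE size factors or with spots of at least 5000 UMIs. In every case below the cause was not tested, except that leaving out sections or spots lowers the data by construction. In the order whole section, cortex, hippocampus and white matter, PSAPP_CO against WT_CO (3, 3, 2 and 1 genes) gave 5, 89 and 29 in the last 3 areas without the filter on low counts. There it gave 6, 8 and 2 with the replicate block and 1, 1 and 0 without Prnp. It gave 19, 6, 4 and 2 with DESeq2, 1 and 3 in the hippocampus and white matter without the plane sections, and 1 and 2 there at double cluster resolution. PSAPP_TAM against PSAPP_CO (191, 278, 220 and 0) gave 126, 185, 115 and 1 without the plane sections and 87 and 104 in the cortex and hippocampus without the Cst7-led cluster. It gave 473 and 39 in the hippocampus and white matter without the filter and 358 and 25 with the block. It gave 317 in the whole section and 2 in the white matter with DESeq2, and 13 in the white matter from only the 2 groups. WT_TAM against WT_CO (0, 0, 1 and 0) gave 1 and 3 in the whole section and cortex and 10 in the white matter without the plane sections, and 10 and 1 in the whole section and cortex with DESeq2. From only the 2 groups it gave 2 in the whole section and 3 in the hippocampus. It gave 56 and 110 in the hippocampus and white matter without the filter, 129 in the white matter with the block and 0 in the hippocampus at double resolution. The interaction (4 and 62 in the whole section and cortex) gave 29 and 132 without the filter, 13 and 453 with the block and 13 and 4 without the plane sections. It gave 162 and 184 with DESeq2, 37 with region-balanced sums and 2 in the cortex without the Cst7-led cluster. Lists called for PSAPP_CO against WT_CO (10 in the whole section and 10 in the cortex) were 0 and 0 with an estimated correlation and 1 and 0 with fry. For WT_TAM against WT_CO (5 and 4) they were 0 and 0 with either, 3 with region-balanced sums and 7 in the cortex with the block. Genes higher in anchor-positive spots (639) were 984 with at least 2 UMIs, and the difference by treatment (26) 55 with at least 2 UMIs and 17 with DESeq2. Leaving out each section gave, for PSAPP_CO against WT_CO, 1 to 3, 2 to 3, 1 to 4 and 1 to 2 genes. It was 1 in the whole section without WT_CO 2, 1 in the hippocampus without WT_CO 1, WT_CO 2, PSAPP_CO 1 or PSAPP_CO 2, 4 without PSAPP_CO 3, and 2 in the white matter without WT_CO 2. For PSAPP_TAM against PSAPP_CO it gave 84 to 205, 170 to 357, 118 to 293 and 0 to 5 genes. The whole-section count was 84 without PSAPP_TAM 1, 87 without PSAPP_CO 2, 92 without PSAPP_CO 3 and 115 without PSAPP_TAM 2, and the cortex count 170 without PSAPP_TAM 1. The hippocampus count was 118 without PSAPP_TAM 1, 127 without PSAPP_CO 1 and 145 without PSAPP_CO 2 or PSAPP_TAM 2, and the white matter count was 5 without WT_TAM 3 and 1 without WT_CO 1 or WT_TAM 1. For WT_TAM against WT_CO it gave 0 to 0, 0 to 0, 0 to 2 and 0 to 0, with 0 in the hippocampus without WT_CO 1, WT_CO 2, WT_TAM 1 or WT_TAM 3 and 2 without PSAPP_TAM 1. For the interaction it gave 0 to 11 in the whole section and 30 to 84 in the cortex. The whole-section count was 0 without WT_CO 1, WT_CO 2, PSAPP_CO 2, PSAPP_CO 3, PSAPP_TAM 1 or PSAPP_TAM 3, 7 without WT_TAM 1, 8 without PSAPP_CO 1, 9 without WT_TAM 3 and 11 without WT_CO 3. The cortex count was 30 without PSAPP_CO 1, 31 without WT_CO 1, 34 without PSAPP_TAM 1, 40 without PSAPP_CO 2 and 41 without WT_TAM 1. Anchor-spot genes numbered 430 to 688, those by treatment 6 to 46. The differences in share were 2.057 to 3.031, 6.069 to 8.087, 0.176 to 0.634 and 5.23 to 6.239 points. The third, WT_TAM against WT_CO (0.39), was 0.634 without WT_TAM 1 and 0.176 without WT_TAM 3. Without thinning, 24.705% of spots in PSAPP_TAM and 9.108% in PSAPP_CO were positive, and with at least 2 UMIs 3.04 and 0.601%. Every section correlated best with a section of its own number in the hippocampus (12 of 12), and 7 did in the whole section, 9 in the cortex and 9 in the white matter, a hint from the data and not the design. In the 2 comparisons whose pairs all exceeded 0.1, the block changed no call of a gene named by the rule, and of the list calls only that of the synapse list. A fit with Xist as a covariate was not run, since its level did not differ enough between sections. Depth limits the low end: the white matter sums held at most 3.17 M UMIs.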

Other observations

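All tests in this part were chosen only after the first results were seen. In the amygdala and piriform area, 31 genes rose in PSAPP_TAM over PSAPP_CO and 0 fell, of 12167 tested (edgeR, 520 at an unadjusted p under 0.05). Ifi27l2a rose by 3.12 log2 units (adjusted p = 0.00124) and Cd9, a tetraspanin of activated microglia, by 1.15. Of the disease-associated list, 8 of 21 members rose (14 adjusted over the list alone, median 0.85), of the plaque-induced list 23 of 52 (41, median 0.83), of the lysosome list 6 of 24 (17, median 0.45), of the complement list 3 of 8 (7, median 1.09) and of the reactive astrocyte list 4 of 8 (5, median 0.90). In the striatum, hypothalamus and thalamus edgeR called 0 genes, with 542 of 12679, 423 of 14685 and 440 of 14160 at an unadjusted p under 0.05. Values there went the same way for several members: adjusted over the list alone, 10 of 20 disease-associated genes rose in the striatum (median 0.43) and 9 of 22 in the hypothalamus (0.33), and 1 of 22 in the thalamus (0.24). The interferon list had 11 of 16 members higher in the hypothalamus when adjusted over the list alone (median 1.21). The log2 fold change of Inpp5d in the thalamus was -1.49 (unadjusted p = 0.00117) and did not pass. Whether these regions differ from the cortex was not tested. The other splits of the 6 sections, too few for a share under 0.05, gave at most 15 genes in the amygdala and piriform area (real 31, 1 of 10 splits), 61 in the striatum (real 0, 10), and 0 in the hypothalamus and thalamus (real 0, 10 each).

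Spots adjacent to anchor-positive spots in the PSAPP cortex differed from farther spots in some microglial and in most listed myelin genes. Of 13767 genes, 35 were higher and 58 lower in adjacent than in farther spots (1114 at an unadjusted p under 0.05). Of the 372 genes at least 1.5-fold higher in positive spots and tested here, 307 lay above 0 in adjacent spots and 27 passed, with a median of 0.17 over farther spots, where that of positive spots over all other spots was 1.33. Ccl3 (1.2), Ccl6 (1.01, adjusted p = 0.000843), Lyz2 (0.70, adjusted p = 0.00144), Tyrobp (0.68, adjusted p = 5.43e-07) and Trem2 (0.50) were higher, and Nr4a2 (-0.44) and Cryab (-0.35) lower. Of the disease-associated list, 7 of 22 members were higher and 1 lower. The homeostatic microglia list had 1 of 13 higher, and the plaque-induced list 22 of 52. Of the myelin list, 11 of 12 members were lower (median -0.45), among them Plp1 (-0.51), Mobp (-0.49), Cldn11 (-0.49) and Opalin (-0.49). Adjacent and farther spots were not matched for cortical layer. Both classes lacked anchor UMIs only after thinning, and 828 of these 3870 spots (21.4%) held a UMI of Cst7 or Itgax at full depth. Whether such spots lay more often next to positive spots was not tested, so they could account for part of the microglial rise. Transcripts that spread between neighbouring spots and cells that lie across spots were not separated.

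Between tamoxifen-treated groups, the cortex of PSAPP_TAM differed from that of WT_TAM in 357 of 15649 genes, 333 higher and 24 lower (1870 at an unadjusted p under 0.05). Of the disease-associated list 21 of 24 were higher (median 1.58), of the homeostatic list 12 of 13, of the complement list 10 of 12 (median 1.71), of the interferon list 15 of 19, and of the reactive astrocyte list 4 of 14 (9 adjusted over the list alone, median 0.84). This comparison uses the library labelled WT_TAM 1. The real split gave 357 genes and the highest other split 1 (1 of 10 splits, too few for a share under 0.05).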
